A study of Mus musculus with 48 samples.

How the data were processed

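Per the labels, total RNA was taken up in Trizol, cleaned with DNase treatment and labelled as biotinylated cRNA. The authors deposited scanner tables of mean bead signals that were not normalised (unit: intensity), each with a detection p-value against negative control probes. They also deposited a value table. Its 30 reprogramming columns hold linear intensities with medians from 2919 to 2922, and its 18 ESC and EpiSC columns hold log2 values that the authors quantile normalised, with a median of 7.59 each. The scale and centring of the linear columns, and the method that adjusted them between plates, are not given in the sources used here. Over genes, the median SD of the plate means was 0.0018 log2 in those columns and 0.214 log2 in the normalised scanner signals. The scanner software and the culture and sorting steps are not given in the sources used here.

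The scanner signals were background corrected and quantile normalised over all 48 arrays in log2 with limma's neqc, which infers the background from the detection p-values. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with Python 3.11.15 and matplotlib 3.10.9 for figures. Of 25697 probes, 23978 had 1 gene symbol, 0 several and 1719 none, and no symbol was updated. The probe with the highest mean stood for each of 16593 genes. A gene was tested when its detection p was under 0.05 on at least 3 arrays of the fit. Reprogramming arrays were fitted together (30 arrays, 10947 genes), as were ESC and EpiSC arrays (18 arrays, 9958 genes). All 48 arrays were fitted for iPSC against ESC (11315 genes). Groups were those of the labels.

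Changed means a Benjamini-Hochberg adjusted p under 0.05 in limma with a mean-variance trend, over all genes of a comparison, and 23 comparisons were made. Log2 values carry the standard error of limma (SE). Folds are unsigned, and the sentence gives the direction. Where a gene was detected on no array of 1 group, a bound is printed. It sets the bright group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among detected probes. Beside chance at 10%, the share of tested genes whose 2 groups of 3 arrays did not overlap ranged from 22.6% (Sall4+OSK red against green) to 63.1% (OSK yellow against black).

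The 20 gene lists (370 genes, 326 on the array) were tested with camera at a preset correlation of 0.01. Of 103 list results printed with a camera test, 91 passed, and 64 of these also passed with an estimated correlation, the others being marked where printed. The Sall family and sex chromosome lists had too few members for camera. Positions were compared with two-sided exact permutation tests.

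Before the data were examined, the groups, comparisons, lists, most alternatives and the choice of genes to name were fixed. Genes to name were the 10 highest and 10 lowest among changed genes with non-overlapping groups (for the interaction, without that condition), names beginning with LOC, Gm or EG or holding Rik left out. Added were up to 4 members of each list with the largest change, and Pou5f1, Sox2, Klf4, Sall4, Nanog, Esrrb, Zfp42, Dppa5a, Fgf5, Otx2, Cdh1, Thy1 and Col1a1. Not all of them are printed. The alternatives were no background correction, median scaling, the authors' value table, other detection filters, all named probes, array weights, fits of only the groups compared, plate and replicate blocks, and leaving out each array. The 2 chosen after the data were seen were a fit without the Sall4+OSK sorted arrays that carried number 3 or no number, and the order of the unnumbered yellow arrays.

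Replicate numbers were checked for pairing by correlating, between 2 groups, each number's deviation from its group mean. It passed for 8 comparisons. Number 3 lay on another plate than numbers 1 and 2, and for the difference of 1 and 2 alone r was 0.0359 to 0.233 in these. The labels leave pairing by number open, and the main fits were unpaired. The number of arrays limits the precision. Changes are relative to the scaling, and the shift of the median of all genes is printed where median scaling moved it by more than 0.1 log2.

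The fit was tried on simulated data with 200 of 10947 genes changed, at the variances of OSK red against black. It called 16%, 58.7% and 93.3% of genes changed by 0.5, 1 and 2 log2, with 7 false among 129 calls. A first limit on the share called at 1 log2 was not met and was replaced after the result was seen. Of 19 unshifted lists 0 were called.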

Results

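RNA from 48 mouse samples was measured on Illumina MouseRef-8 v2 bead arrays, which carry 25697 probes. The samples formed 16 groups of 3, and the design text describes the triplicates as independent lines. Reprogramming cells of the B6 strain carried either OSK, the pluripotency factors Oct4 (gene Pou5f1), Sox2 and Klf4, or the same factors with Sall4, a zinc finger protein of pluripotent cells. Each cocktail gave 4 sorted fractions called black, red, yellow and green, and induced pluripotent stem cells (iPSCs). The series title names miR-290 and miR-302, microRNA clusters of pluripotent cells, as the sorted markers, and the labels do not define the colours. From background knowledge, not from the sources used here, the red reporter is taken to mark miR-290, green miR-302, yellow both and black neither. The remaining groups were embryonic stem cells (ESCs) in Lif and inhibitors (Lif2i), ESC dR (day 1), dY (day 4), dG and dB (both day 7) of differentiation, and epiblast stem cells (EpiSCs), the primed counterpart of ESCs.

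The arrays lay on 5 plates. OSK sorted arrays 1 and 2 were on plate 1, and their array 3 and the OSK iPSCs on plate 2. Sall4+OSK sorted arrays 1 and 2 were on plate 3, and their array 3 and the Sall4+OSK iPSCs on plate 4. ESC and EpiSC arrays were on plate 5. Of the 3 Sall4+OSK yellow arrays, 2 shared a column name and are treated as carrying no number. Median probe signal ran from 119 to 268 units per array and was highest on plate 3, where it ran from 186 to 268. Between 42.9% and 53.8% of probes were detected. Replicate arrays correlated at r of at least 0.985 in the OSK groups. In the Sall4+OSK sorted groups the lowest r between replicates was 0.934, and in ESC Lif2i it was 0.956.

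The cocktail factors themselves were read first. Pou5f1 RNA was high in every reprogramming group, at a mean of 11.98 ± 0.138 log2 (SD, n = 3) in OSK black and 11.52 ± 0.441 (SD, n = 3) in Sall4+OSK black. Sall4 was read by several probes that disagreed. One probe of Sall4, ILMN_2676148, was detected on no OSK array and on all Sall4+OSK sorted arrays, with bounds of at least 11.2-fold in black, 5.13-fold in red, 5.9-fold in green and 1.66-fold in yellow. The brighter Sall4 probe used below was lowest, among the reprogramming groups, in the black fractions, at 8.92 ± 0.151 log2 (SD, n = 3) in OSK black and 7.41 ± 0.554 (SD, n = 3) in Sall4+OSK black.

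Each sorted array was then placed on the line from the black mean (0) to the iPSC mean (1) of its cocktail. OSK red lay at 0.195 ± 0.00899, OSK green at 0.246 ± 0.012 and OSK yellow at 0.501 ± 0.0227 (SD, n = 3 each). Sall4+OSK red lay at 0.324 ± 0.128, green at 0.344 ± 0.0996 and yellow at 0.652 ± 0.0812 (SD, n = 3 each). All yellow arrays lay above all red and green arrays of their cocktail (two-sided exact permutation p = 0.1 for each pair, the smallest that 3 against 3 arrays allow). Red minus green was -0.0518 with OSK (exact permutation p = 0.1) and -0.0204 with Sall4+OSK (exact permutation p = 0.7), and the latter turned positive without red 1, red 2 or green 3, which leaves the plates unequal. By number, which keeps to 1 plate, it was -0.0527, -0.019 and 0.0105. Sall4+OSK black, red and green 3, on plate 4 with the iPSCs, lay nearer to the iPSC end than numbers 1 and 2, so the SD and p include plate.

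**Figure D1:**
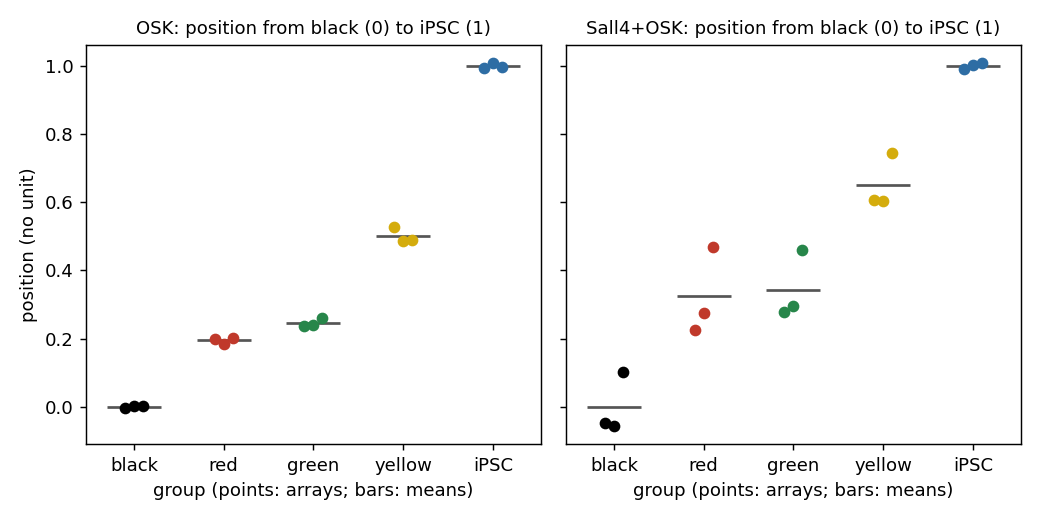
Position of each sorted and iPSC array on the line from the black mean (0) to the iPSC mean (1) of its cocktail, without unit; points are arrays and bars are group means. The yellow arrays of OSK lie between 0.487 and 0.527, above every red and green array of OSK.

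The first question was how cells sorted as red, green or yellow differed from the black fraction of the same OSK cultures.

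OSK red cells carried more RNA of naive pluripotency genes than black cells, and less of fibroblast genes. Esrrb (28.4-fold, log2 4.83 ± 0.12 SE, adjusted p = 5.26e-19), an orphan nuclear receptor of naive ESCs, rose, beside the X-linked homeobox genes Rhox9 (26.2-fold), Rhox6 (24.2-fold) and Rhox5 (15.6-fold). The de novo methylation cofactor Dnmt3l (at least 11.4-fold, adjusted p = 1.59e-11) and the pluripotency-associated Dppa5a (14.6-fold) and Dppa4 (14.7-fold, detected on 1 of 3 black arrays) were higher. Collagen Col1a1 (10.3-fold, log2 -3.36 ± 0.43 SE, adjusted p = 1.21e-06) and the mesenchymal receptor Pdgfra (8.9-fold) were lower, as were Dlk1 (11.5-fold), Sostdc1 (10.9-fold) and Ptn (10-fold). In the naive pluripotency list 10 of 19 rose, 1 fell and 8 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 7.93e-07), and in the general pluripotency list 8 of 15 rose, 1 fell and 6 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 3.12e-06), with Nanog (3.48-fold) and Sall4 (5.15-fold) higher. Fibroblast and mesenchymal genes went the other way, where 25 of 27 fell and 2 did not pass (25 adjusted over the list alone, camera adjusted p = 9.22e-21), among them Lox (8.57-fold), Lum (8.32-fold) and Thy1 (6.67-fold). Of the epithelial list 13 of 19 rose and 6 did not pass (14 adjusted over the list alone, camera adjusted p = 1.12e-08), led by the tight junction gene Cldn4 (6.38-fold) and E-cadherin Cdh1 (4.84-fold). Cell cycle genes such as Mcm2 (1.91-fold) and Cdt1 (1.84-fold) were higher, since 15 of 19 rose and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 1.22e-07). In the TGF-beta and EMT response list 9 of 14 fell and 5 did not pass (10 adjusted over the list alone, camera adjusted p = 6.63e-07), among them Inhba (5.88-fold) and Bgn (4.76-fold). The delivered factor Pou5f1 (log2 -0.47 ± 0.19 SE, adjusted p = 0.074) did not pass, but did with the replicate block (adjusted p = 0.00034). By limma, 2753 of 10947 genes changed, 1423 higher and 1330 lower. With plate as a block 4296 genes passed, with the replicate number as a block 4474, and within plate 1 3167.

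OSK green cells likewise gained pluripotency transcripts and lost fibroblast ones against black cells. Esrrb (35.4-fold, log2 5.15 ± 0.12 SE, adjusted p = 1.17e-19), Dppa5a (19.6-fold) and the oocyte and ESC gene Ooep (13.2-fold) were among the highest, together with Nkx6-1 (13.9-fold), a homeobox gene of neural and pancreatic progenitors, and the methyltransferase Dnmt3b (10.9-fold). Matrix genes Eln (38.9-fold, detected on 2 of 3 green arrays), Lum (26.5-fold) and Mgp (24.2-fold) and Col1a1 (29.1-fold, log2 -4.86 ± 0.43 SE, adjusted p = 2.08e-09) fell. Among the naive genes 10 of 19 rose, 3 fell and 6 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.000288). Of the primed epiblast list 8 of 19 rose and 11 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00108, adjusted p = 0.0573 with an estimated correlation), with Igfbp2 (4.88-fold) and Lefty2 (4.28-fold) higher. Fibroblast genes were lower, since 1 of 27 rose, 23 fell and 3 did not pass (1 and 24 adjusted over the list alone, camera adjusted p = 4.05e-17), and Thy1 (1.98-fold) fell less than the collagens. In the cell cycle list 15 of 19 rose and 4 did not pass (16 adjusted over the list alone, camera adjusted p = 8.27e-09), with Cdc20 (2.14-fold) higher. Immediate early genes were lower in green, where 8 of 15 fell and 7 did not pass (8 adjusted over the list alone, camera adjusted p = 0.000624), among them Egr2 (2.64-fold), Dusp1 (2.56-fold) and Ier3 (2.36-fold). Ifit3 (9.33-fold) was lower and Rsad2 (3.31-fold) higher. Among the reported miR-290 and miR-302 targets 4 of 9 fell and 5 did not pass (5 adjusted over the list alone, camera adjusted p = 0.068, adjusted p = 0.0449 with the replicate block), with the TGF-beta receptor Tgfbr2 (6.02-fold) lower. In total 3489 genes changed, 1891 higher and 1598 lower, with 4973 past the threshold under the plate block and 3796 within plate 1.

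Among the OSK fractions, yellow cells had the most changed genes against black. Dnmt3l (at least 278-fold, adjusted p = 1.78e-18), Aire (at least 51.4-fold, adjusted p = 2.08e-15) and Rbmxl2 (at least 39.2-fold, adjusted p = 4.95e-19) and Esrrb (169-fold, log2 7.40 ± 0.12 SE, adjusted p = 2.15e-23) rose, as did Dppa4 (216-fold, detected on 1 of 3 black arrays), Dppa5a (82.8-fold), Dnmt3b (73.7-fold) and Tex19.1 (67.3-fold), genes of pluripotent or germ cells. The epiblast regulator Otx2 (at least 15-fold, adjusted p = 8.66e-15) and the epiblast growth factor Fgf5 (at least 4.8-fold, adjusted p = 3.62e-12), neither detected in black cells, were also higher. Igfbp3 (21.2-fold) and Gsn (at least 8.24-fold, adjusted p = 3.17e-12) and Col1a1 (15.3-fold, log2 -3.93 ± 0.43 SE, adjusted p = 2.57e-08) fell. In the naive list 15 of 19 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 8.83e-07). In the primed epiblast list 13 of 19 rose and 6 did not pass (13 adjusted over the list alone, camera adjusted p = 2e-06), with Cldn6 (at least 27.5-fold, adjusted p = 3.93e-17) higher. Fibroblast genes were lower, since 25 of 27 fell and 2 did not pass (25 adjusted over the list alone, camera adjusted p = 6.15e-12). The splicing regulator Esrp1 (at least 27.2-fold, adjusted p = 2.08e-05) rose. Germline genes were higher, where 8 of 11 rose and 3 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00139). Interferon genes were lower, as 1 of 15 rose, 10 fell and 4 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 0.00139), with Isg15 (4.62-fold) and Irf7 (4.42-fold) among them. Endoderm genes Dab2 (7.03-fold) and Gata6 (at least 3.05-fold, adjusted p = 5.73e-07) fell. The glucose transporter Slc2a1 (4.01-fold) rose, and in the glycolysis list 11 of 15 rose, 2 fell and 2 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.00115). Of the miR-290 and miR-302 targets 1 of 9 rose, 7 fell and 1 did not pass (2 and 7 adjusted over the list alone, camera adjusted p = 0.00379), with Tgfbr2 (6.68-fold) and Irf2 (3.15-fold) lower. Among sex chromosome transcripts 1 of 3 rose and 2 did not pass (1 adjusted over the list alone), namely Uty (1.65-fold). The kept probes of Sox2 and Klf4 fell, by log2 fold changes of -2.14 and -1.86, while another Klf4 probe rose by 2.60 and another Sox2 probe was detected on all yellow and no black arrays. The count was 5614 genes, 2834 higher and 2780 lower. Under the plate block it was 6972, and within plate 1 it was 5999.

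Set directly against each other, OSK red cells carried more epithelial RNA than OSK green cells. Gpnmb (28.8-fold), Rhox9 (18.5-fold, log2 4.21 ± 0.23 SE, adjusted p = 8.48e-13), Rhox6 (14.8-fold), Ltf (16.6-fold) and Saa3 (15.2-fold) were higher in red. Nkx6-1 (28.4-fold, detected on 1 of 3 red arrays), Dbx1 (16.4-fold) and Slc1a3 (13.1-fold) and Napsa (15-fold) were higher in green. In the epithelial list 10 of 19 rose and 9 did not pass (10 adjusted over the list alone, camera adjusted p = 2.23e-05), with Cldn4 (6.99-fold), Krt8 (4.39-fold), Rab25 (2.7-fold) and Cdh1 (2.66-fold) higher in red. The naive list was divided, as 4 of 19 rose, 4 fell and 11 did not pass (5 and 5 adjusted over the list alone, camera adjusted p = 0.998), with Klf2 (2.58-fold) higher and Gbx2 (3.62-fold) and Jam2 (2.78-fold) lower in red. Primed genes Pou3f1 (3.77-fold), Igfbp2 (2.58-fold) and Otx2 (at least 1.28-fold, adjusted p = 0.0293) were lower in red, where 1 of 19 rose, 5 fell and 13 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.148). Among fibroblast genes Lum (3.19-fold) and Col1a1 (2.83-fold) were higher and Thy1 (3.37-fold) and Zeb2 (3.13-fold) lower in red, and 10 of 27 rose, 5 fell and 12 did not pass (13 and 6 adjusted over the list alone, camera adjusted p = 0.169, adjusted p = 0.0414 with the replicate block). Immediate early genes Hspa1a (2.27-fold) and Ier3 (2.2-fold) were higher in red. Red and green differed in 2000 genes, 964 higher and 1036 lower in red. The count was 3196 under the plate block, 3363 under the replicate block, 2340 within plate 1 and 3116 when the fit held only these 6 arrays.

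The next comparison took the OSK iPSCs against the yellow cells. Acta1 (at least 84.9-fold, adjusted p = 4.73e-20), Myl3 (at least 25.8-fold, adjusted p = 3.96e-12) and Krt18 (20.5-fold) and the lysozyme genes Lyz1 (62.3-fold, detected on 1 of 3 yellow arrays) and Lyz2 (at least 19.9-fold, adjusted p = 1.13e-10) rose. Slc38a5 (52.9-fold, log2 -5.73 ± 0.20 SE, adjusted p = 3.97e-17), Samd9l (at least 92.2-fold, adjusted p = 5.58e-19), Aoc1 (at least 116-fold, adjusted p = 6.3e-20), Slc7a11 (at least 62.9-fold, adjusted p = 1.35e-21) and Psg23 (56-fold) fell. Interferon genes fell together, where 1 of 15 rose, 12 fell and 2 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 6.79e-05), with Oasl2 (27.4-fold), Usp18 (22.9-fold) and Isg15 (6.17-fold) lower. Naive genes Tcl1 (10.6-fold), Pecam1 (6.66-fold), Dppa3 (6.6-fold) and Zfp42 (3.45-fold) rose, and 8 of 19 rose, 6 fell and 5 did not pass (10 and 6 adjusted over the list alone, camera adjusted p = 0.163). Fgf5 (at least 3.91-fold, adjusted p = 3.57e-12) and Dnmt3b (4.1-fold) fell and Pou5f1 (3.34-fold) rose. Of the epithelial list 10 of 19 rose, 4 fell and 5 did not pass (10 and 4 adjusted over the list alone, camera adjusted p = 0.0209, adjusted p = 0.163 with an estimated correlation), with Krt19 (at least 10.4-fold, adjusted p = 1.24e-11) higher. For glycolysis 11 of 15 rose and 4 did not pass (12 adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.163 with an estimated correlation). In total 5283 genes changed, 2528 higher and 2755 lower in iPSCs, with 6254 under the plate block and 5449 within plate 2.

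The same fractions were compared in cells that had also received Sall4.

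In Sall4+OSK cells, red carried more RNA of pluripotency genes and less of fibroblast genes than black. Dnmt3l (at least 259-fold, adjusted p = 1.93e-17), Tex19.1 (at least 56.4-fold, adjusted p = 4.32e-17) and Utf1 (at least 40.1-fold, adjusted p = 1.25e-16) and Dppa5a (74.2-fold, log2 6.21 ± 0.14 SE, adjusted p = 3.1e-20), all linked to pluripotent or germ cells, rose, with Dppa4 (77-fold) and Gpx2 (59.9-fold). Ogn (4.69-fold), Matn4 (4.21-fold), Col15a1 (4.17-fold) and Isg15 (3.98-fold) were among the lowest. In the general pluripotency list 11 of 15 rose, 1 fell and 3 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 1.09e-12). Among naive genes 14 of 19 rose, 2 fell and 3 did not pass (14 and 3 adjusted over the list alone, camera adjusted p = 2.52e-08), with Dppa3 (at least 14.4-fold, adjusted p = 2.76e-12) and Klf2 (4.81-fold) higher. The primed epiblast list also rose, as 14 of 19 rose and 5 did not pass (14 adjusted over the list alone, camera adjusted p = 1.42e-11), with Otx2 (28.2-fold) and Cldn6 (28.5-fold) and Fgf5 (at least 10.6-fold, adjusted p = 5.28e-14) higher. Endoderm genes Amn (24.5-fold), Ttr (6.58-fold) and Dab2 (4.2-fold) were higher, and 10 of 15 rose, 3 fell and 2 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0004). Of the immune cell list 6 of 10 rose and 4 did not pass (7 adjusted over the list alone, camera adjusted p = 0.00055, adjusted p = 0.0646 with an estimated correlation), with Lyz2 (5.18-fold), Fcer1g (3.89-fold) and Coro1a (3.27-fold) higher. Fibroblast genes fell, since 21 of 27 fell and 6 did not pass (24 adjusted over the list alone, camera adjusted p = 5.1e-10), with Tagln (3.79-fold) and Col1a1 (3.51-fold) lower. The kept Sall4 probe rose by 4.68 log2 while the probe absent from OSK cells was at -1.02. In all 3668 genes changed, 1838 higher and 1830 lower. The count was 5321 under the plate block, 4334 within plate 3 and 1758 when only these groups were fitted.

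Sall4+OSK green cells gained genes of the epiblast. Fgf15 (at least 24.9-fold, adjusted p = 1.45e-12) and Wnt8a (at least 16.6-fold, adjusted p = 2.22e-11) and Lefty2 (23.5-fold, log2 4.56 ± 0.20 SE, adjusted p = 1.31e-14), all signalling ligands, rose with Otx2 (17.5-fold), Fzd10 (19.2-fold, detected on 2 of 3 black arrays) and Utf1 (at least 14.7-fold, adjusted p = 7.36e-14). Lox (14.1-fold), Mgp (15-fold) and Col1a1 (13.2-fold) fell. In the primed epiblast list 13 of 19 rose and 6 did not pass (13 adjusted over the list alone, camera adjusted p = 3.26e-10), with Fgf8 (at least 12-fold, adjusted p = 3.91e-09) and Fgf5 (at least 6.36-fold, adjusted p = 3.44e-12) higher. Among naive genes 10 of 19 rose, 2 fell and 7 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.00898), with Ooep (4.22-fold) higher. Fibroblast genes were lower, as 24 of 27 fell and 3 did not pass (24 adjusted over the list alone, camera adjusted p = 4.07e-14). Mesoderm genes were divided, since 4 of 9 rose, 4 fell and 1 did not pass (4 and 4 adjusted over the list alone, camera adjusted p = 0.958), with Isl1 (3.41-fold) and Gsc (2.08-fold) higher and Pdgfra (5.46-fold) and Bmp4 (2.54-fold) lower. In the cell cycle list 16 of 19 rose and 3 did not pass (16 adjusted over the list alone, camera adjusted p = 5.99e-11), with Mcm7 (3.22-fold) and Cdt1 (2.95-fold) higher. The p53 and senescence list was lower, where 6 of 12 fell and 6 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00132), with Fas (4.19-fold), Cdkn2b (3.73-fold) and Cdkn1a (1.98-fold) lower. The result was 4249 genes, 2121 higher and 2128 lower, and 1648 genes were higher and 2716 lower with median scaling in place of quantile normalization. Under the plate block 5712 passed, within plate 3 4843, and 2440 when only these groups were fitted.

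Sall4+OSK yellow cells had the most changed genes against black of their cocktail. Dnmt3l (at least 249-fold, adjusted p = 7.48e-18), Utf1 (at least 82.9-fold, adjusted p = 3.7e-18) and Eras (at least 49.3-fold, adjusted p = 1.88e-17) and Dppa4 (96.4-fold, log2 6.59 ± 0.21 SE, adjusted p = 7.28e-18), genes of pluripotent cells, rose with Gpx2 (82.7-fold) and Dppa5a (75.2-fold). Ogn (28.7-fold), Lum (19.2-fold), Mgp (22.1-fold) and Col1a1 (17.5-fold) fell. Fibroblast genes fell together, where 27 of 27 fell (27 adjusted over the list alone, camera adjusted p = 7.33e-12). In the primed epiblast list 16 of 19 rose and 3 did not pass (16 adjusted over the list alone, camera adjusted p = 1.67e-08), with Otx2 (59.2-fold), Cldn6 (38.7-fold) and Car14 (20.8-fold) and Fgf5 (at least 27-fold, adjusted p = 6.24e-17) higher. Among naive genes 12 of 19 rose, 4 fell and 3 did not pass (12 and 4 adjusted over the list alone, camera adjusted p = 0.00298), with Dppa3 (at least 22.1-fold, adjusted p = 4.82e-14) higher. Epithelial genes rose, as 15 of 19 rose and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 1.88e-05), with Rab25 (at least 47.8-fold, adjusted p = 2.82e-15) and Cldn4 (23.6-fold) higher. Of the neural list 1 of 13 rose, 5 fell and 7 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 0.363), with Stmn2 (2.96-fold) lower. Trophectoderm genes were divided, since 2 of 9 rose, 3 fell and 4 did not pass (2 and 3 adjusted over the list alone, camera adjusted p = 0.844), with Gata2 (11.8-fold) and Tfap2a (5.64-fold) lower and Tfap2c (3.29-fold) higher. Of the Sall family 4 of 4 rose (4 adjusted over the list alone), with Sall1 (2.77-fold) and Sall2 (1.73-fold) higher, while the Sall4 probe absent from OSK cells changed by -2.42 log2. The number of changed genes was 6087, 3064 higher and 3023 lower. With plate as a block it was 7329 or 6384, and within plate 3 7074 or 4207, depending on which unnumbered yellow array was taken as number 2.

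Between red and green of the Sall4+OSK cells, red carried more naive, endoderm, fibroblast and immune cell RNA. Dnmt3l (11.9-fold, log2 3.57 ± 0.27 SE, adjusted p = 2.15e-09), Dppa3 (7.21-fold) and Gpx2 (9.65-fold) were higher in red. Igdcc3 (6.53-fold), Fzd10 (7.29-fold) and Nkx6-1 (5.89-fold) and the ligand Wnt8a (at least 16.4-fold, adjusted p = 2.26e-09) were higher in green. Among naive genes 12 of 19 rose, 2 fell and 5 did not pass (13 and 3 adjusted over the list alone, camera adjusted p = 6.26e-07), with Klf2 (3.54-fold), Zfp42 (3.12-fold) and Klf5 (2.94-fold) higher in red. Endoderm genes Amn (5.72-fold), Dab2 (4.03-fold) and Ttr (3.29-fold) were higher in red, as 9 of 15 rose and 6 did not pass (10 adjusted over the list alone, camera adjusted p = 3.51e-07). In the immune cell list 6 of 10 rose and 4 did not pass (6 adjusted over the list alone, camera adjusted p = 4.01e-05), with the macrophage genes Lyz2 (at least 9.22-fold, adjusted p = 1.46e-07) and C1qb (at least 3.18-fold, adjusted p = 1.05e-07) higher in red. Fibroblast genes were higher in red too, where 14 of 27 rose and 13 did not pass (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.26e-07, adjusted p = 0.066 with an estimated correlation), with Lox (4.2-fold), Lum (3.78-fold) and Col1a1 (3.74-fold) among them. Cell cycle genes were lower in red, since 5 of 19 fell and 14 did not pass (11 adjusted over the list alone, camera adjusted p = 4.01e-05), with Top2a (1.51-fold) lower. Primed genes Fgf8 (3.81-fold) and Lefty2 (3.37-fold) were lower and Otx2 (1.61-fold) higher in red, and 7 of 19 rose, 4 fell and 8 did not pass (8 and 4 adjusted over the list alone, camera adjusted p = 0.958). The count was 1868, 1119 higher and 749 lower in red, or 1481 higher and 515 lower with median scaling and 1326 higher and 1396 lower from the authors' value table. Under the plate block 3309 genes passed, under the replicate block 3507, within plate 3 1729 and with only these groups 373.

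Sall4+OSK iPSCs, set against yellow, carried more naive and germline RNA and less of primed and endoderm genes. The germ cell genes Dazl (21.1-fold, detected on 2 of 3 yellow arrays) and Asz1 (28.5-fold, detected on 1 of 3 yellow arrays) and Tcl1 (13.8-fold, log2 3.78 ± 0.25 SE, adjusted p = 1.74e-11) rose, with Cdyl2 (at least 14.3-fold, adjusted p = 1.51e-15) and Zscan4c (at least 8.75-fold, adjusted p = 4.39e-08). Klk1 (27.4-fold), Ttr (at least 13.5-fold, adjusted p = 1.01e-10), Prelp (at least 15.5-fold, adjusted p = 4.64e-15), Bcl11a (at least 14.5-fold, adjusted p = 2.92e-12) and Car4 (20.8-fold) fell. In the naive list 16 of 19 rose, 1 fell and 2 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 1.81e-08), with Nr5a2 (6.42-fold), Zfp42 (4.41-fold) and Esrrb (3.29-fold) higher. Among germline genes 8 of 11 rose and 3 did not pass (8 adjusted over the list alone, camera adjusted p = 2.56e-06). The primed epiblast list was lower, as 1 of 19 rose, 10 fell and 8 did not pass (1 and 10 adjusted over the list alone, camera adjusted p = 1.16e-05), with Pou3f1 (14-fold) and Car14 (13.7-fold) and Fgf5 (at least 20.4-fold, adjusted p = 1.36e-15) lower. Endoderm genes fell, where 12 of 15 fell and 3 did not pass (12 adjusted over the list alone, camera adjusted p = 1.71e-08), with Dab2 (10.9-fold) and Gata6 (6.9-fold) lower. Acta2 (9.62-fold) and Thy1 (4.06-fold) fell. In this contrast 4406 genes changed, 2513 higher and 1893 lower. Under the plate block the count was 4592 or 3400 and within plate 4 3316 or 5335, by the order of the unnumbered yellow arrays. Of 200 genes low on the plate 4 arrays (median -2.14 log2 here), 34 fell. On these 200 genes the unnumbered array a stood at 9.34 log2 and b at 5.83, and the first count of each pair takes b as number 3. In the authors' value table Acta2 0.77 and Klk1 0.31 had the other sign (log2).

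The effects of colour could be set against each other across the cocktails, which share no arrays. For red against black 843 genes were higher in both cocktails, where independent lists would share 239, and 811 lower in both (222 for independent lists). For yellow against black the numbers were 2131 higher (793) and 2076 lower (768). For red against green they were 348 (98.5) and 288 (70.9), with 131 genes called in opposite directions. For iPSC against yellow they were 1191 (580) and 956 (476), with 549 in opposite directions. Pearson's r of the log2 changes across genes, which are not independent replicates, was 0.545 for red against black, 0.662 for green against black, 0.765 for yellow against black, 0.32 for red against green and 0.42 for iPSC against yellow.

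**Figure D2:**
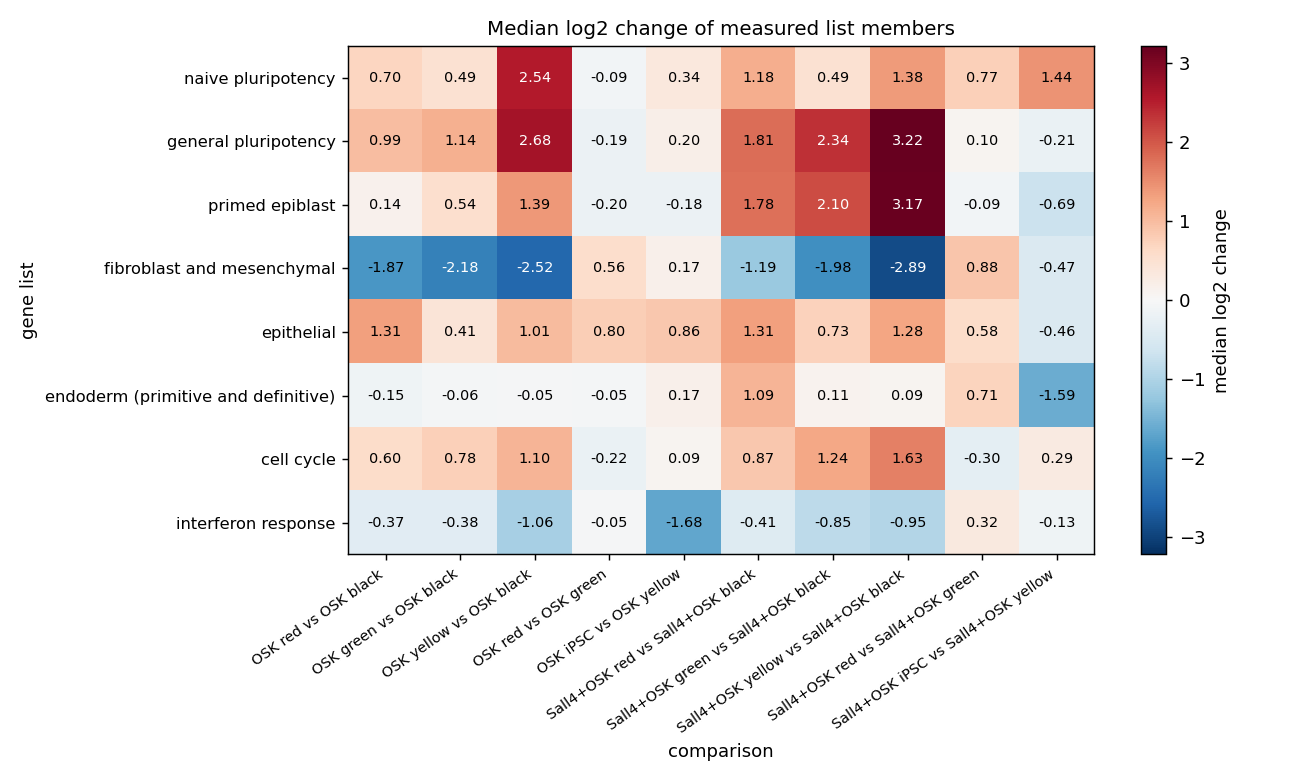
Median log2 change of 8 gene lists in 10 comparisons between sorted fractions, with rows as lists, columns as comparisons and colour from lower (blue) to higher (red). The fibroblast and mesenchymal list is lower in red, green and yellow against black in both cocktails.

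The effect of adding Sall4 was read within each colour. The cocktails lay on different plates, so these comparisons also hold any difference between plates, and each count is given with plate as a random block.

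In the black fraction, Sall4 went with lower interferon response genes and with higher Esrrb (38.6-fold, log2 5.27 ± 0.12 SE, adjusted p = 6.67e-20). Mt3 (158-fold, detected on 1 of 3 OSK arrays), Timp4 (at least 45.4-fold, adjusted p = 1.27e-17), Klk10 (54.3-fold) and Cytl1 (at least 19.7-fold, adjusted p = 5.15e-13) also rose. Slc17a6 (at least 80.5-fold, adjusted p = 8.55e-17), Ltf (at least 38.5-fold, adjusted p = 3.37e-15), Mmp13 (at least 20.8-fold, adjusted p = 1.93e-10) and Avil (60.6-fold) fell. Interferon genes fell, as 13 of 15 fell and 2 did not pass (13 adjusted over the list alone, camera adjusted p = 7.32e-10), with Isg15 (11.6-fold), Ifit3 (11.2-fold) and Rsad2 (10.2-fold) lower. In the primed epiblast list 9 of 19 rose and 10 did not pass (9 adjusted over the list alone, camera adjusted p = 0.000403, adjusted p = 0.0829 with an estimated correlation), with Igfbp2 (6.36-fold), Pou3f1 (4.69-fold) and Cldn6 (at least 3.87-fold, adjusted p = 1.79e-10) higher. Endoderm genes Gata6 (9.68-fold) and Ttr (at least 4.86-fold, adjusted p = 2.54e-07) were higher, and 6 of 15 rose and 9 did not pass (7 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.0829 with an estimated correlation). In the authors' value table the medians of these lists had the other sign (log2 -0.06 for primed and -0.01 for endoderm), as had Cldn6 -0.73, Gata6 -0.0815, Igfbp2 -0.21, Pou3f1 -0.44, Rsad2 0.12 and Ttr -0.11. Naive genes were divided, where 7 of 19 rose, 4 fell and 8 did not pass (8 and 5 adjusted over the list alone, camera adjusted p = 0.225), with Gbx2 (12.9-fold) higher and Socs3 (2.61-fold) lower. The kept Sall4 probe was lower with Sall4, with a change of -1.51 log2, and the probe absent from OSK cells higher, as given above. In all 3353 genes changed, 1708 higher and 1645 lower, and 2617 with plate as a random block. With median scaling 2801 genes were higher and 1081 lower, with the median of all genes at 0.13 log2 in place of 0.00.

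Red cells that had received Sall4 carried more endoderm, primed and immune cell RNA than OSK red cells. Spink1 (at least 157-fold, adjusted p = 5.17e-14), Foxq1 (at least 48.6-fold, adjusted p = 5.61e-16), Ttr (at least 29.7-fold, adjusted p = 9.83e-13) and Ctsh (at least 51.7-fold, adjusted p = 3.15e-13) and Pou3f1 (49.8-fold, log2 5.64 ± 0.20 SE, adjusted p = 9.08e-17) rose, with Gata6 (49-fold) and Amn (47.8-fold). Ltf (at least 48.6-fold, adjusted p = 9.46e-16), Avil (84.1-fold), Kng2 (38.6-fold) and Myh1 (117-fold, detected on 2 of 3 Sall4+OSK arrays) fell. In the endoderm list 10 of 15 rose and 5 did not pass (11 adjusted over the list alone, camera adjusted p = 2.56e-07), with Dab2 (31.4-fold) higher. In the primed list 15 of 19 rose and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 6.04e-10), with Otx2 (at least 32.6-fold, adjusted p = 4.88e-16), Fgf5 (at least 9.71-fold, adjusted p = 9.3e-15) and Cldn6 (36.2-fold) higher. Interferon genes fell, where 1 of 15 rose, 13 fell and 1 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 1.9e-07), with Isg15 (29.7-fold) and Usp18 (14.5-fold) lower. Among immune cell genes 7 of 10 rose and 3 did not pass (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000935, adjusted p = 0.111 with an estimated correlation), with Lyz2 (at least 9.38-fold, adjusted p = 1.02e-07), Fcer1g (at least 4.63-fold, adjusted p = 1.19e-07) and C1qb (at least 3.23-fold, adjusted p = 3e-08) higher. Utf1 (26-fold) and Dnmt3b (15.3-fold) were higher, and among naive genes 11 of 19 rose, 5 fell and 3 did not pass (11 and 5 adjusted over the list alone, camera adjusted p = 0.00262), with Tbx3 (10.9-fold, detected on 2 of 3 OSK arrays) and Dppa3 (at least 13.2-fold, adjusted p = 3.31e-12) higher. The count was 4301, 2293 higher and 2008 lower, with 3574 under the random plate block and 2303 from the authors' value table.

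In green cells interferon genes were lower and primed genes higher with Sall4. Gata6 (39.6-fold, log2 5.31 ± 0.27 SE, adjusted p = 1.48e-13), Spink1 (at least 72.5-fold, adjusted p = 2.84e-12), Igdcc3 (22.6-fold), Lefty2 (20.1-fold) and Fgf8 (at least 11.4-fold, adjusted p = 1.37e-09) rose. Glra2 (59.4-fold), Oas2 (38.1-fold), Pkp1 (24.2-fold) and Avil (25.3-fold) fell. Interferon genes fell, as 14 of 15 fell and 1 did not pass (14 adjusted over the list alone, camera adjusted p = 9.85e-13), with Isg15 (28.9-fold, detected on 2 of 3 Sall4+OSK arrays), Usp18 (22.1-fold) and Irf7 (at least 7.19-fold, adjusted p = 5.95e-14) lower. In the primed list 13 of 19 rose and 6 did not pass (15 adjusted over the list alone, camera adjusted p = 9.85e-13), with Otx2 (15.9-fold) and Cldn6 (13.8-fold) higher. Endoderm genes Dab2 (17.4-fold) and Apoa1 (at least 4.56-fold, adjusted p = 9.01e-06) rose, and 7 of 15 rose, 1 fell and 7 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.0746 with an estimated correlation). That list's median was -0.02 log2 in the authors' value table, where Avil 0.34, Cldn6 -0.12, Dab2 -0.16 and Otx2 -0.0925 also had the other sign. Fas (3.29-fold) and Mdm2 (1.7-fold) were lower and Igfbp3 (4.92-fold) and Krt18 (4.67-fold) higher. In total 3652 genes changed, 1793 higher and 1859 lower, 2899 with plate as a random block and 1525 from the authors' value table.

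In yellow cells endoderm and primed genes were higher and naive and interferon genes lower with Sall4. Spink1 (at least 63.6-fold, adjusted p = 3.54e-12), Gata6 (at least 22-fold, adjusted p = 6.33e-13) and Ttr (at least 14-fold, adjusted p = 7.3e-11) and Dab2 (19.5-fold, log2 4.28 ± 0.24 SE, adjusted p = 6.95e-13) rose, with Foxq1 (at least 14.8-fold, adjusted p = 2.08e-13) and Car4 (31.6-fold, detected on 1 of 3 OSK arrays). Aldh3a1 (27.9-fold), Oas2 (42.4-fold), Avil (43.7-fold) and Aoc1 (20.6-fold) fell. In the authors' value table, which evens out the plate means, they stood at log2 1.497, 0.47, 1.79 and 1.01. In the endoderm list 10 of 15 rose, 1 fell and 4 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 3.8e-06), with Amn (14.6-fold) higher, and in the primed list 14 of 19 rose, 1 fell and 4 did not pass (15 and 1 adjusted over the list alone, camera adjusted p = 2.12e-08), with Car14 (11.3-fold), Zic2 (7.48-fold, detected on 2 of 3 OSK arrays), Fgf8 (13.1-fold, detected on 1 of 3 OSK arrays), Fgf5 (5.53-fold) and Otx2 (4.92-fold) higher. Naive genes were lower, where 2 of 19 rose, 10 fell and 7 did not pass (2 and 11 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.0501 with an estimated correlation), with Socs3 (7.09-fold), Esrrb (2.45-fold) and Nr5a2 (2.53-fold) lower and Fgf4 (3.48-fold) higher. Interferon genes fell, as 1 of 15 rose, 12 fell and 2 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 2.12e-08), with Usp18 (46.9-fold, detected on 1 of 3 Sall4+OSK arrays) and Isg15 (15.6-fold, detected on 1 of 3 Sall4+OSK arrays) lower. In the authors' value table the median of the interferon list was 0.04 log2, and Gata6 -0.17, Isg15 0.26, Socs3 0.11 and Usp18 0.17 had the other sign. The count was 4143, 2009 higher and 2134 lower, and 3347 or 3734 under the random plate block. Median scaling gave another split, in which 2827 genes were higher and 1397 lower, with the median of all genes at 0.08 log2 in place of -0.04.

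Sall4+OSK iPSCs carried less mesenchymal and TGF-beta response RNA than OSK iPSCs. Acta2 (37.2-fold, log2 -5.22 ± 0.28 SE, adjusted p = 3.56e-13), Acta1 (102-fold, detected on 1 of 3 Sall4+OSK arrays), Igfbp7 (93.7-fold, detected on 1 of 3 Sall4+OSK arrays), Cav1 (at least 22.3-fold, adjusted p = 6.7e-06) and Krt8 (18.3-fold) fell. Dctn1 (at least 15.4-fold, adjusted p = 1.77e-09), Asz1 (21.3-fold, detected on 1 of 3 OSK arrays), Spen (at least 8.44-fold, adjusted p = 7.81e-08) and Arfgef3 (8.71-fold) rose. In the TGF-beta list 11 of 14 fell and 3 did not pass (11 adjusted over the list alone, camera adjusted p = 6.62e-08), with Bgn (17.1-fold), Inhba (19.4-fold, detected on 1 of 3 Sall4+OSK arrays) and Thbs1 (at least 7.85-fold, adjusted p = 1.73e-09) lower. Fibroblast genes were lower, as 1 of 27 rose, 17 fell and 9 did not pass (1 and 17 adjusted over the list alone, camera adjusted p = 6.62e-08, adjusted p = 0.116 with an estimated correlation), with Lox (14.6-fold), Col1a1 (7.59-fold) and Thy1 (4.33-fold) lower. Klf4 (3.1-fold), Klf2 (2.25-fold), Dazl (7.5-fold) and Rhox5 (3-fold) were higher, while another Klf4 probe was at -1.36 log2 (adjusted p = 0.163). Of the epithelial list 2 of 19 rose, 9 fell and 8 did not pass (2 and 9 adjusted over the list alone, camera adjusted p = 0.00226, adjusted p = 0.0951 with an estimated correlation), with Krt18 (10.5-fold) and Krt19 (8.45-fold, detected on 2 of 3 Sall4+OSK arrays) lower. Otx2 (5.79-fold) and Zic2 (at least 6.72-fold, adjusted p = 1.92e-07) were higher and Pou5f1 (2.43-fold) lower. In all 4926 genes changed, 2873 higher and 2053 lower. Of 200 genes low on the plate 4 arrays (median -2.33 log2 here), 85 fell. Here plate and group cannot be told apart, since all OSK iPSCs lay on plate 2 and all Sall4+OSK iPSCs on plate 4, and with plate as a random block over the other groups 3127 genes passed. With median scaling 3894 genes were higher and 1138 lower, with the median of all genes at 0.18 log2 in place of 0.05.

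**Figure D3:**
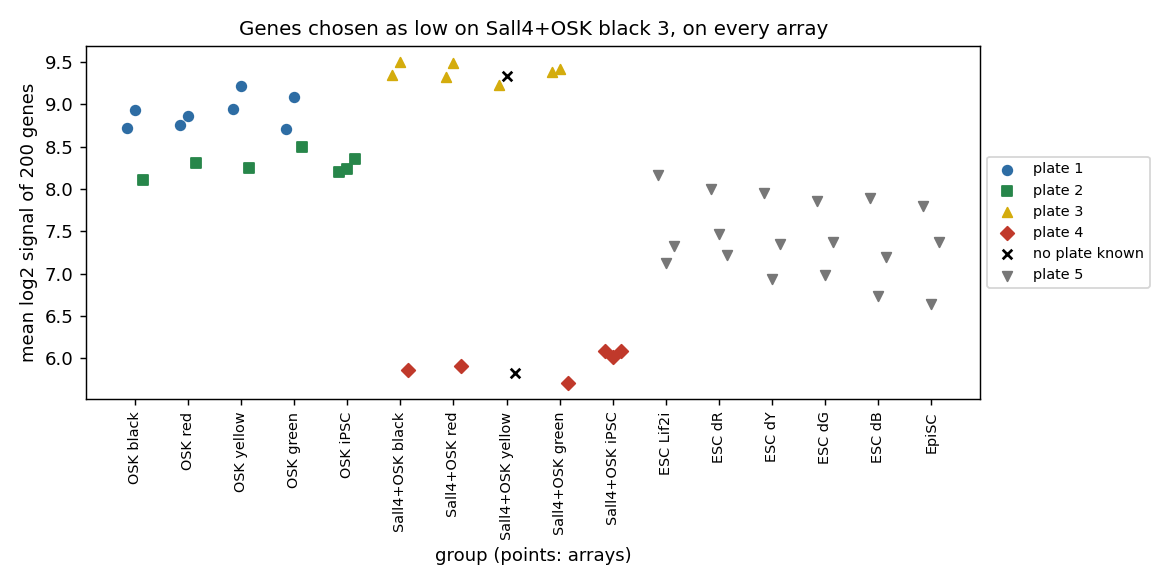
Mean log2 signal, on each array of the 16 groups, of 200 genes chosen as lowest on Sall4+OSK black 3; points are arrays and shapes are plates. The Sall4+OSK iPSC arrays of plate 4 lie near 6.08 log2 and OSK iPSC 1 at 8.20.

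Whether red and green differed in another way with Sall4 was tested as an interaction, red minus green with Sall4+OSK less red minus green with OSK, in log2. The difference was positive for Dnmt3l (3.57 ± 0.38 SE, adjusted p = 1.82e-07) and the endocytic adaptor gene Amn (3.93 ± 0.39 SE, adjusted p = 8.21e-08), and for Ooep (2.38) and Pou3f1 (2.72). It was negative for Gvin1 (-3.89 ± 0.38 SE, adjusted p = 4.89e-08) and Rhox9 (-1.79). Only genes detected on at least 1 array of each of the 4 groups are named here. Naive genes tended to positive differences (counted here as rose), where 7 of 19 rose, 1 fell and 11 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 7.98e-06). Endoderm genes did too, as 5 of 15 rose and 10 did not pass (7 adjusted over the list alone, camera adjusted p = 7.98e-06), and so did immune cell genes, since 6 of 10 rose and 4 did not pass (6 adjusted over the list alone, camera adjusted p = 2.38e-06). The interaction called 1267 genes, 782 positive and 485 negative, and with median scaling 995 genes were higher and 385 lower, with the median of all genes at 0.11 log2 in place of 0.01. With plate as a block it called 2356, with the replicate block 2531, within plates 1 and 3 1440, and from the authors' value table there were 1129 higher and 1112 lower.

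**Figure D4:**
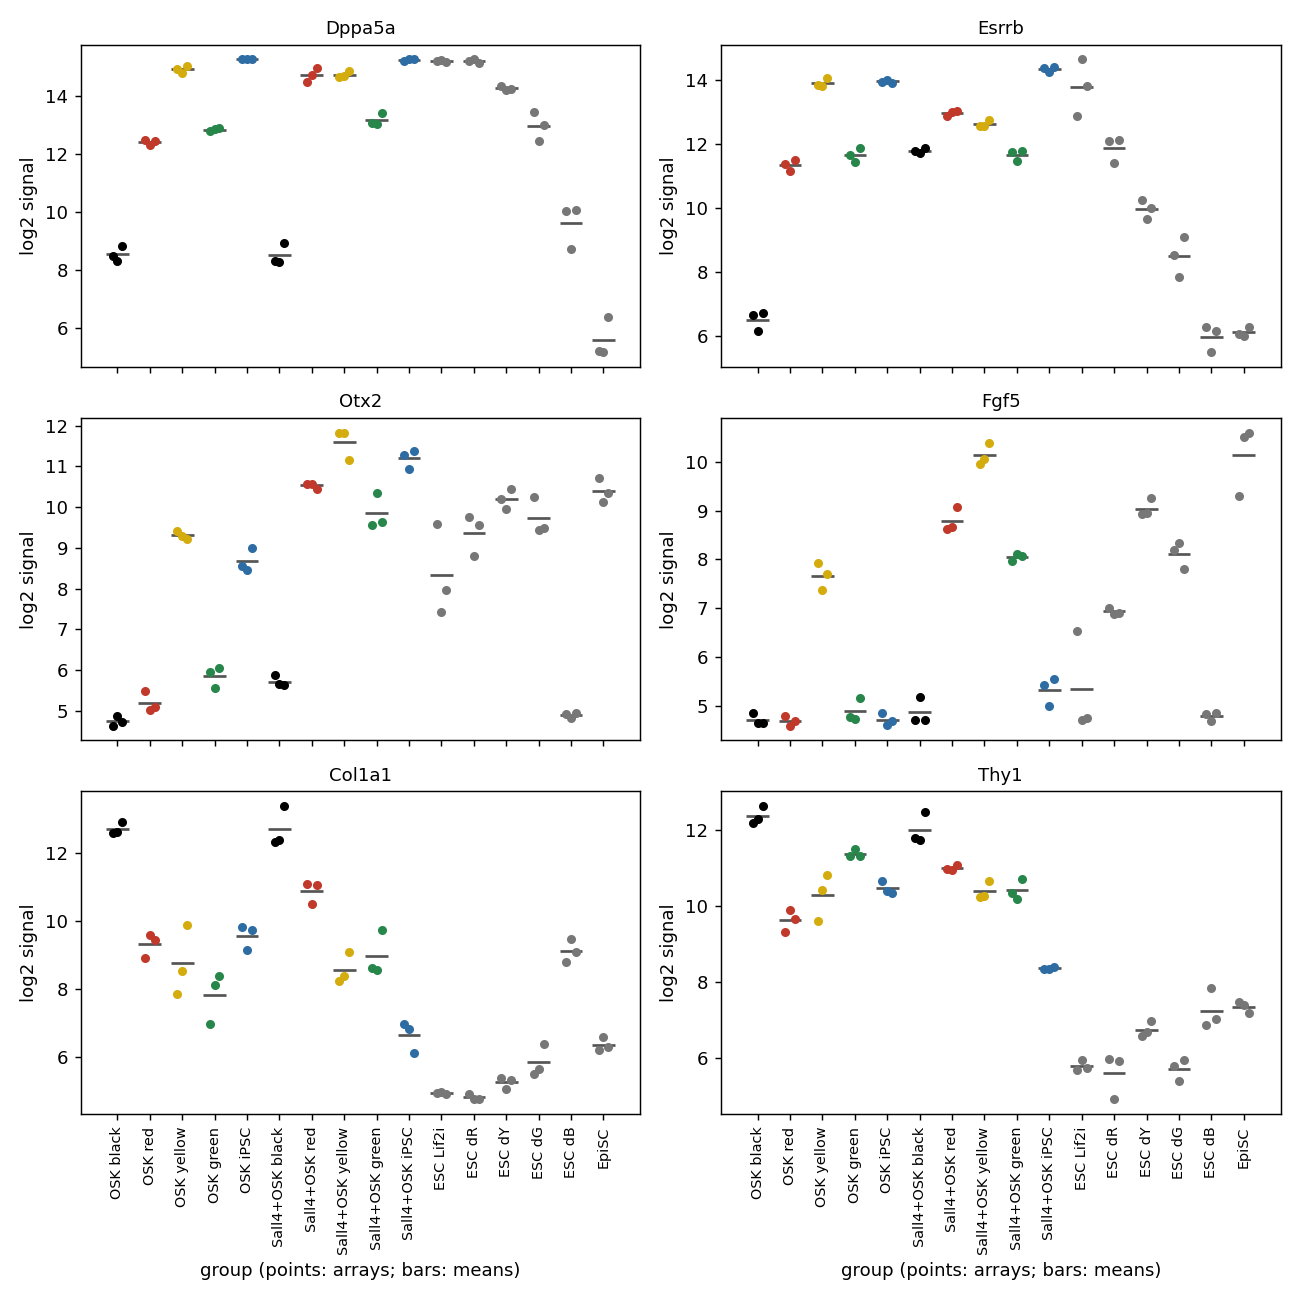
Log2 signal of 6 genes on each array of the 16 groups; points are arrays and bars are group means. Esrrb in OSK black averages 6.52 and in Sall4+OSK black 11.79 log2.

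Differentiating ESCs and EpiSCs gave a reference for leaving the naive state. One of the ESC Lif2i arrays, replicate 1, stood apart from the other 2 in these genes, with Klf4 at 7.47 against up to 10.58 log2 among the ESC Lif2i arrays.

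At day 1, ESC dR cells had less naive pluripotency RNA than ESCs in Lif2i. Tbx3 (22.3-fold, log2 -4.48 ± 0.41 SE, adjusted p = 1.42e-05), Klf4 (16.6-fold, detected on 1 of 3 dR arrays), Esrrb (3.76-fold), Nr5a2 (6.21-fold) and Tcl1 (7.37-fold) fell, as did Sp5 (at least 13.3-fold, adjusted p = 5.04e-05), Mapt (at least 23.8-fold, adjusted p = 9.61e-05) and Bmp4 (18.7-fold, detected on 1 of 3 dR arrays). Lefty1 (5.93-fold), Etv1 (5.37-fold, detected on 2 of 3 Lif2i arrays), Vrtn (6.18-fold, detected on 2 of 3 Lif2i arrays) and Fgf5 (3.03-fold, detected on 1 of 3 Lif2i arrays) rose. Among naive genes 2 of 19 rose, 9 fell and 8 did not pass (2 and 12 adjusted over the list alone, camera adjusted p = 4.14e-05, adjusted p = 0.32 with an estimated correlation). Gbx2 went against its list (mean 12.07 log2 in Lif2i 2 and 3, 13.43 in dR). In the primed list 8 of 18 rose and 10 did not pass (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00417, adjusted p = 0.32 with an estimated correlation), with Pou3f1 (3.79-fold), Lefty2 (3.73-fold) and Sall2 (3.49-fold) higher. Trophectoderm genes fell, where 5 of 8 fell and 3 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00397, adjusted p = 0.32 with an estimated correlation), with Tead4 (10.6-fold) and Tfap2c (8.96-fold) lower. Without ESC Lif2i replicate 1 most of these changes were larger, at log2 -5.20 for Tbx3, -5.04 for Klf4, -3.28 for Nr5a2 and 3.75 for Lefty1. By limma 2126 of 9958 genes changed, 1001 higher and 1125 lower. Without ESC Lif2i replicate 1 the count was 3444, without replicate 2 531 and without replicate 3 697. It was 1341 with median scaling, 6314 with array weights and 0 when only these groups were fitted in limma, where 1868 genes had an unadjusted p under 0.05.

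At day 4, ESC dY cells had less naive RNA and more neural and mesenchymal RNA than ESCs in Lif2i. Esrrb (14-fold, log2 -3.81 ± 0.38 SE, adjusted p = 3.86e-07), Klf4 (at least 14.8-fold, adjusted p = 9.93e-06), Tbx3 (29.1-fold, detected on 2 of 3 dY arrays), Zfp42 (8.27-fold) and Gpx2 (48.4-fold) fell. Crabp2 (26.2-fold), Nuak1 (33-fold), Efnb1 (28-fold), Fgf8 (39.5-fold, detected on 1 of 3 Lif2i arrays) and Igfbp5 (48.4-fold, detected on 2 of 3 Lif2i arrays) rose. In the naive list 15 of 19 fell and 4 did not pass (15 adjusted over the list alone, camera adjusted p = 2.53e-09, adjusted p = 0.067 with an estimated correlation). In the primed list 12 of 18 rose, 1 fell and 5 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 0.000236, adjusted p = 0.0762 with an estimated correlation), with Fgf5 (13.1-fold, detected on 1 of 3 Lif2i arrays) and Otx2 (3.67-fold) higher and Mreg (7.83-fold) lower. Neural genes rose, as 10 of 14 rose and 4 did not pass (10 adjusted over the list alone, camera adjusted p = 0.000129, adjusted p = 0.0762 with an estimated correlation), with Zic1 (at least 10.8-fold, adjusted p = 1.4e-08) and Map2 (7.7-fold, detected on 2 of 3 Lif2i arrays) higher. Of the fibroblast list 17 of 24 rose and 7 did not pass (17 adjusted over the list alone, camera adjusted p = 8.97e-07, adjusted p = 0.067 with an estimated correlation), with Mmp2 (12.4-fold) and Acta2 (at least 11.2-fold, adjusted p = 2.37e-09) higher. Cdh1 (4.42-fold) and Cldn4 (6.5-fold) fell. In all 3998 genes changed, 2060 higher and 1938 lower. With median scaling 1590 genes were higher and 2095 lower, with the median of all genes at -0.15 log2 in place of -0.04, and with array weights 6770 genes passed.

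At day 7, ESC dG cells were also set against ESCs in Lif2i. Esrrb (39-fold, log2 -5.29 ± 0.38 SE, adjusted p = 3.21e-09), Zfp296 (50.8-fold, detected on 2 of 3 dG arrays), Laptm5 (58.8-fold), Gpx2 (54.7-fold) and Dppa5a (4.72-fold) fell, and the neural genes Dcx (at least 38-fold, adjusted p = 3.82e-10), Lhx5 (at least 34.6-fold, adjusted p = 1.29e-12), Dpysl4 (64.1-fold) and Nrcam (34.6-fold, detected on 1 of 3 Lif2i arrays) rose. Among naive genes 1 of 19 rose and 18 fell (1 and 18 adjusted over the list alone, camera adjusted p = 6.24e-09, adjusted p = 0.0737 with an estimated correlation). The general pluripotency genes Dnmt3l (17.8-fold) and Utf1 (13.7-fold) were lower, and Sall4 (log2 -0.35 ± 0.20 SE, adjusted p = 0.155) did not pass. Neural genes rose, where 10 of 14 rose and 4 did not pass (10 adjusted over the list alone, camera adjusted p = 6.15e-06, adjusted p = 0.0737 with an estimated correlation), with Zic1 (at least 28.2-fold, adjusted p = 1.81e-10) higher. Cdh1 (11.3-fold) fell. Germline genes fell, as 8 of 12 fell and 4 did not pass (8 adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.133 with an estimated correlation), with Rhox5 (5.2-fold) lower. Among reported miR-290 and miR-302 targets 5 of 9 rose and 4 did not pass (5 adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.0843 with an estimated correlation), with Irf2 (at least 11.8-fold, adjusted p = 2.31e-11) and Tgfbr2 (3.57-fold, detected on 2 of 3 Lif2i arrays) higher. The count was 4977, 2430 higher and 2547 lower.

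The day 7 fractions dB and dG differed in pluripotency and mesenchymal genes. Pou5f1 (36.8-fold, log2 -5.20 ± 0.21 SE, adjusted p = 2.14e-11), Sall4 (36.4-fold), Gdf3 (35.5-fold), Nanog (18.1-fold), Lefty1 (48.5-fold) and Otx2 (at least 20.1-fold, adjusted p = 1.04e-07) were lower in dB, and Lum (17.9-fold), Tnc (14.6-fold), Vcam1 (11.8-fold), Gas6 (12.2-fold) and Col1a1 (9.66-fold) higher. In the general list 12 of 15 fell and 3 did not pass (13 adjusted over the list alone, camera adjusted p = 6.11e-18). In the fibroblast list 20 of 24 rose and 4 did not pass (21 adjusted over the list alone, camera adjusted p = 1.29e-20), with Prrx1 (10.3-fold) and Dcn (9.79-fold) higher. In the primed list 1 of 18 rose, 11 fell and 6 did not pass (1 and 12 adjusted over the list alone, camera adjusted p = 1.92e-09). Klf4 (4.15-fold, detected on 2 of 3 dG arrays) and Tgfbr2 (9.33-fold) were higher and Dppa5a (10.2-fold) lower. Glycolysis genes were lower in dB, where 10 of 15 fell and 5 did not pass (10 adjusted over the list alone, camera adjusted p = 3.18e-06, adjusted p = 0.087 with an estimated correlation), with Slc2a1 (5.72-fold) lower. In total 2119 genes changed, 1072 higher and 1047 lower, with 3846 under array weights and 1410 without ESC dG replicate 1.

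EpiSCs carried less of most naive transcripts than ESCs. Esrrb (203-fold, log2 -7.66 ± 0.38 SE, adjusted p = 2.35e-11), Dppa5a (786-fold, detected on 1 of 3 EpiSC arrays), Ooep (at least 178-fold, adjusted p = 2.55e-13), Dppa4 (at least 216-fold, adjusted p = 3.04e-13) and Dnmt3l (at least 106-fold, adjusted p = 6.09e-12) fell, while Pou5f1 (log2 0.38 ± 0.21 SE, adjusted p = 0.161) did not pass. Acta2 (at least 119-fold, adjusted p = 9.24e-13), Fgf8 (74.1-fold, detected on 1 of 3 Lif2i arrays), Fgf5 (28-fold, detected on 1 of 3 Lif2i arrays), Tnc (at least 16.2-fold, adjusted p = 4.85e-10) and Car14 (23.6-fold) rose. In the naive list 17 of 19 fell and 2 did not pass (17 adjusted over the list alone, camera adjusted p = 1.95e-13), with Tbx3 (at least 34.6-fold, adjusted p = 1.95e-09) lower. In the primed list 9 of 18 rose, 4 fell and 5 did not pass (9 and 4 adjusted over the list alone, camera adjusted p = 0.0252, adjusted p = 0.237 with an estimated correlation), with Otx2 (4.2-fold) higher. Epithelial genes fell, as 13 of 16 fell and 3 did not pass (14 adjusted over the list alone, camera adjusted p = 2.84e-07), with Cdh1 (8.78-fold) and Cldn4 (at least 54-fold, adjusted p = 2.27e-11) lower. Tpm1 (5.95-fold) rose. Of the p53 list 9 of 12 rose, 2 fell and 1 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.005), with Ccng1 (3.66-fold) higher and Cdkn2a (4.89-fold) lower. The count was 4230, 2176 higher and 2054 lower.

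The last comparisons set iPSCs against ESCs, which lay on different plates, so plate and group cannot be told apart. Naive calls may depend on ESC Lif2i replicate 1, whose Esrrb was 12.87 log2 against a mean of 14.29 in replicates 2 and 3.

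OSK iPSCs carried more mesenchymal RNA than ESCs. Acta2 (at least 299-fold, adjusted p = 4.28e-25) and Lox (at least 46.4-fold, adjusted p = 1.22e-19), Cav1 (at least 21.2-fold, adjusted p = 4.2e-09) and Igf2 (52.2-fold) were higher, with Bgn (143-fold, detected on 1 of 3 Lif2i arrays), Fbln2 (at least 48.5-fold, adjusted p = 6.47e-22) and Lyz1 (at least 61.9-fold, adjusted p = 6.03e-15). Aoah (19.9-fold), Erich5 (14.3-fold) and Dctn1 (at least 11.8-fold, adjusted p = 1.51e-06) were lower. In the fibroblast list 18 of 27 rose, 2 fell and 7 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 4.64e-08), with Thy1 (25.6-fold, detected on 1 of 3 Lif2i arrays) and Col6a1 (at least 18.6-fold, adjusted p = 8.38e-22) higher. For the TGF-beta list 10 of 14 rose and 4 did not pass (11 adjusted over the list alone, camera adjusted p = 4.64e-08), with Inhba (at least 14.2-fold, adjusted p = 4.16e-19) higher. Naive genes were divided, as 6 of 19 rose, 6 fell and 7 did not pass (6 and 7 adjusted over the list alone, camera adjusted p = 0.931), with Dppa3 (7.41-fold) and Fgf4 (5.39-fold) higher and Gbx2 (4.75-fold) lower, and Esrrb (log2 0.18 ± 0.27 SE, adjusted p = 0.645) did not pass. Epithelial genes were higher, where 11 of 19 rose, 1 fell and 7 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 9.76e-06), with Krt18 (24.1-fold) and Krt8 (5.53-fold) higher. By limma 5012 of 11315 genes changed, 2359 higher and 2653 lower. With median scaling 1169 genes were higher and 4600 lower, with the median of all genes at -0.36 log2 in place of -0.05.

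Sall4+OSK iPSCs differed from ESCs in germline genes, among them Dazl (23.3-fold, detected on 1 of 3 Lif2i arrays) and Asz1 (11.4-fold), and in Igfbp4 (19.3-fold, log2 4.27 ± 0.24 SE, adjusted p = 7.08e-17) and Ldhc (at least 17.6-fold, adjusted p = 3.61e-19) and Pdzk1 (46-fold, detected on 1 of 3 Lif2i arrays), all higher. Atf5 (15.5-fold), Sp5 (at least 13.1-fold, adjusted p = 8.01e-11), Olig1 (at least 12.1-fold, adjusted p = 1.05e-14) and Krtdap (at least 8.32-fold, adjusted p = 1.5e-11) were lower. Among germline genes 8 of 12 rose and 4 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.255 with an estimated correlation), with Rhox5 (5.16-fold) higher. In the naive list 4 of 19 rose, 3 fell and 12 did not pass (4 and 3 adjusted over the list alone, camera adjusted p = 0.727), with Dppa3 (6.95-fold) and Fgf4 (8.1-fold) higher and Gbx2 (5.04-fold) and Zfp42 (1.93-fold) lower. For glycolysis 9 of 15 rose and 6 did not pass (9 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.269 with an estimated correlation), with Pfkl (4.32-fold) higher. Thy1 (5.91-fold, detected on 1 of 3 Lif2i arrays), Otx2 (7.34-fold) and Cldn6 (11.8-fold) were higher and Pou5f1 (2.62-fold) lower. In all 4874 genes changed, 2601 higher and 2273 lower. Of 200 genes low on the plate 4 arrays (median -1.62 log2 here), 44 fell. With median scaling 1624 genes were higher and 3515 lower, with the median of all genes at -0.19 log2 in place of -0.01.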

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

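The interaction and the test of single probes were fixed before, and the other tests in this part were chosen only after the result was seen. The interaction test drew out 1 result, a difference between cocktails: red minus green differed with and without Sall4 in 1267 genes (limma, adjusted p under 0.05). Its named genes were Amn (3.93), Dnmt3l (3.57), Pou3f1 (2.72) and Ooep (2.38) in the positive direction and Gvin1 (-3.89) and Rhox9 (-1.79) in the negative, in log2. Median log2 differences were 1.51 for the immune cell list, 0.81 for naive pluripotency and 0.78 for endoderm.

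For this difference 3 of 100 splits, the real one included, gave as many genes. Exchanging the Sall4+OSK red and green labels, which sums the colour effects, gave the most, 2678, so splits set no chance level. The plate 4 arrays as the whole cause are argued against by the 1703 genes past the threshold when the Sall4+OSK sorted arrays with number 3 or no number were left out, a test that replaced the plate block, which leaves these balanced estimates unchanged. Immune cells among the Sall4+OSK red cells remain open for the immune genes. Of 7 list genes detected on no ESC Lif2i array, 6 were higher in Sall4+OSK red than green, and Ctss was detected in neither. Detection in red alone was enough to test these 6, so the count cannot decide this. C1qa, detected on 1 ESC Lif2i array, did not pass (adjusted p = 0.344), nor did Laptm5 and Coro1a, detected on all 3. Immune cells could be carried by a sort gate on red signal alone, which the labels do not describe, and an untested effect of Sall4 stays open.

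A group of 200 genes was low on the plate 4 arrays, chosen as the lowest on Sall4+OSK black 3 against black 1 and 2, among them Kpnb1, Eed and Vapa (named after their values were seen). In Sall4+OSK iPSC minus OSK iPSC, arrays not used to choose them, their median log2 difference was -2.33, as a plate effect shared by the cell types on plate 4 would give. A trait of the third line alone is argued against, since Sall4+OSK iPSC replicates 1 and 2 were also lower, with a median of -2.29 log2 in the replicate nearer to OSK. The shift lay in single probes: the 56 other probes of these genes moved by a median of 0.10 log2 in red and green, where the chosen probes moved by -3.62. A failure of single probes on that plate could account for the shift, and its origin stays open.

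ESC Lif2i replicate 1 stood apart from replicates 2 and 3, with a naive minus primed score of 2.00 log2 against 4.34 and 3.81. A swap with an ESC dR array is argued against, as the highest ESC dR score was 1.26. A culture mixed with cells like those of day 1 could give most of the values, since the 25 list genes implied a median share of 79.95% day 1 signal (quartiles 71.3% and 89.5%), though single genes ran from 19.4% (Fgf4) and 21.9% (Nanog) to 116% (Otx2). No biological explanation was tested, and a wrong label with an outside sample stays open.

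For groups of 3 against 3, the arrays make 10 splits, too few for a share under 0.05. For ESC dR against Lif2i 2 of 10 splits gave as many genes. The other, which put ESC Lif2i 1 with ESC dR 1 and 3, gave 2619 against the real 2126. In every other comparison only 1 of 10, the real one, did. Their highest others were 933 (Sall4+OSK iPSC against ESC), 844 (Sall4+OSK green against black), 843 (Sall4+OSK red against green), 605 (Sall4+OSK red against black) and 577 (OSK iPSC against ESC), and at most 5 elsewhere.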

How the results depend on the processing

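The fit without the Sall4+OSK sorted arrays that carried number 3 or no number, and the order of the unnumbered arrays, were chosen only after the data were seen. No background correction, no or a stricter detection filter and all named probes kept every count of genes within 1.5 times its main value, as did the fit without those Sall4+OSK arrays. Beyond the values below, the counts stayed within 1.5 times under every setting. Of the named genes, 458 kept direction and side of the threshold with median scaling, 463 with array weights and 370 with the authors' value table, where 37 kept direction and lost the threshold. Of the list results, 2 lost the threshold with median scaling, 27 with an estimated correlation and 10 with the authors' table. The authors' table was not run for iPSC against ESC, since it holds them on different scales. Signal over background limits genes detected on no array of a group to the bounds printed.

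Counts of changed genes moved as follows, and the cause was not tested except where given. With array weights they were 4163 (OSK red against black), 3417 (OSK red against green), 6963 (Sall4+OSK iPSC against yellow), 1984 (interaction), 6314 (ESC dR), 6770 (ESC dY) and 3846 (ESC dB against dG). When only the groups compared were fitted, with fewer arrays to estimate the spread, they were 3116 (OSK red against green), 1758 and 2440 (Sall4+OSK red and green against black), 373 (Sall4+OSK red against green) and 0 for ESC dR, where limma gave 1868 genes at an unadjusted p under 0.05. Plate as a fixed block gave 4296 (OSK red against black), 3196 (OSK red against green), 3309 (Sall4+OSK red against green) and 2356 (interaction). As a random block it gave 2100 (interaction) and 3127 (Sall4+OSK against OSK iPSC). The authors' table gave 2303 and 1525 (Sall4+OSK against OSK in red and green) and 2241 (interaction). Median scaling gave 1341 for ESC dR.

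The replicate number as a block, for the pairing that the labels leave open, gave 4474 (OSK red against black), 3363 (OSK red against green), 3507 (Sall4+OSK red against green) and 2531 (interaction). It changed no other call named in the text than those printed beside it.

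Leaving out 1 array moved ESC dR from 531 (without ESC Lif2i replicate 2) to 3444 (without replicate 1), with 697 without replicate 3. ESC dB against dG ran from 1410 (without ESC dG replicate 1) to 2010. The position of red minus green ran from -0.0931 to 0.037 with Sall4+OSK, being 0.0284 without red 1, 0.00362 without red 2 and 0.037 without green 3. With OSK it was -0.112 from the authors' table.

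The authors' table, adjusted between the plates that separate the cocktails, reversed the sign of these log2 changes. In Sall4+OSK against OSK they were, for black, Cldn6 -0.73, Gata6 -0.0815, Igfbp2 -0.21, Pou3f1 -0.44, Rsad2 0.12 and Ttr -0.11. For green they were Avil 0.34, Cldn6 -0.12, Dab2 -0.16 and Otx2 -0.0925. For yellow they were Aldh3a1 1.497, Aoc1 1.01, Avil 1.79, Gata6 -0.17, Isg15 0.26, Oas2 0.47, Socs3 0.11 and Usp18 0.17. In Sall4+OSK iPSC against yellow they were Acta2 0.77 and Klk1 0.31. The list medians that reversed were -0.0132 for endoderm and -0.0584 for primed epiblast in black, -0.0226 for endoderm in green and 0.036 for interferon response in yellow.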

Other observations

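The test of fibroblasts and the score of black cells were chosen only after the result was seen, and the others in this part were written before. Whether green cells hold more of the EpiSC programme than red cells was tested with a score, the mean log2 of genes higher minus that of genes lower in EpiSCs than ESCs. Green minus red was 0.353 log2 with OSK (0.365 within plate 1) and 0.565 with Sall4+OSK (0.509 within plate 3), each with an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The score does not decide it, since it was higher still in black cells, at 0.766 against 0.357 in green with OSK and 0.941 against 0.583 with Sall4+OSK.

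Whether red and green differ as the ESC dR and dG cells do could not be decided. Across genes, which are not independent replicates, Pearson's r between red minus green and ESC dR minus dG was 0.143 with OSK and 0.194 with Sall4+OSK.

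OSK iPSCs held mesenchymal transcripts above ESCs, and fibroblasts like OSK black cells, carried over at one share, are argued against as the cause of the whole pattern. The fibroblast list implied a median share of 11.3% of the OSK black level over 21 genes, ranging from -1.64% to 122%. Dcn, among the genes most abundant in black cells, implied 1.04%, at 7.23 ± 0.472 log2 (SD, n = 3) where the median share would give 10.39. The test first asked for 3 such genes, and 1 was taken as enough after only Dcn was found. Shares were also low, 0.177% for Lum, 0.642% for Col3a1 and 1.1% for Col6a2, against 47% for Lox and 122% for Acta2.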
